A study of Mus musculus with 7 samples.

How the data were processed

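RNA was measured by sequencing in 7 libraries of EML cells, a mouse multipotent haematopoietic progenitor line that gives rise to erythroid, myeloid and lymphoid cells. Per the labels' protocols, apoptotic cells were removed with Annexin V, only Annexin V-negative cells were sorted, and libraries followed standard Illumina steps. The labels place 4 libraries in a CD34-negative group and 3 in a CD34-positive group. A genotype label of the negative libraries reads CD43 where their titles read CD34, and the titles were followed. The tissue label names bone marrow and an age label gives a postnatal day, which are not used here because the source label names the cell line.

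The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), with 1 value per row and library and rows named by gene symbol. Per the submitters' processing notes, TopHat2, TopHat and Cuffdiff were used and the builds mm9 and mm10 are named, without versions and without saying which library each belongs to. The deposited table names genes by symbol only and the build is open, so no genome coordinates are given. Which annotation was used and whether strand was used in counting are not given in the sources used here, so genes that overlap or have near-identical copies, such as the globins and mast cell proteases, are uncertain. All 7 columns of values belong to the 7 libraries.

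FPKM are not counts, and the number of fragments behind them is unknown, so no count model was run and no counting interval can be given. The low values of some library pairs stand in fixed ratios. Among 386 genes with low values in both replicate 1 libraries, 136 had a ratio of CD34-negative to CD34-positive of 0.572 within a narrow window, which would make 1 fragment worth less in the CD34-negative library and its depth 1.75 times greater. Among 469 such genes in CD34-negative and CD34-positive replicate 3, 121 had a ratio of 1.23. The replicate 2 libraries shared no sharp ratio with the others. The deposited columns of replicate 1 hold up to 9 decimals and the other 5 hold 4, and repeated symbols carry different values only in the replicate 2 columns. The libraries were therefore not all written out in the same way.

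The table held 20464 rows. 105 symbols were listed more than once and their 322 rows were left out, among them the list members Hba-a2 and Mecom. Genes with at least 1 FPKM in at least 3 libraries were tested, 9259 in all. Values were transformed as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. The 2 groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend and without robust estimation, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Effects are CD34-positive minus CD34-negative. The standard error is the moderated one. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

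21 gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Member counts are given over all tested genes and adjusted over the list alone. Members were matched by symbol as written. Spi1 is not listed under that symbol in the table used here, and Flt3 was below the minimum. Lists, groups, tests, alternative fits and the rule for named genes were fixed before the data were examined. The rule takes Cd34, the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold whose groups do not overlap and whose higher group averages at least 5 FPKM, up to 4 members of each list with the smallest adjusted p, and Tcf7, Runx1, Gata1, Gata2, Spi1, Kit, Flt3 and Ly6a. No gene passed the threshold, so the ranked part selected none. The same ranking without the adjusted p was added after this was seen. Other list members named here were chosen after their values were seen. Some genes that the rule takes are not reported here.

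The titles number the replicates 1 to 4, and the descriptions carry the numbers 3, 2 and 4, the last for CD34-negative replicates 3 and 4 and CD34-positive replicate 3. Whether these numbers pair the libraries was checked from the correlation of deviations from the group means. It was 0.70 for replicate 1, 0.92 for replicate 2, 0.82 for CD34-negative replicate 3 and 0.85 for CD34-negative replicate 4 with CD34-positive replicate 3. Between libraries of replicates 1 and 2, whose numbers differ, it was 0.09 to 0.37, and for all other libraries of unlike number it was negative. The libraries numbered 4 are also those with a low share of ribosomal protein genes, described below. So 0.82 and 0.85 cannot tell pairing from the kind of library. The numbers were taken to pair the libraries, and a fit with the description number as a block was run. Differences within replicate 3 use the mean of CD34-negative replicates 3 and 4.

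The limma fit was tested on simulated data of 9259 genes, of which 67, 67 and 66 were changed by 1, 2 and 4 on the log2 scale. With libraries paired as here, the fit without a block called 1.5% of genes changed by 1 on the log2 scale, 43.3% of those changed by 2 and 83.3% of those changed by 4, and the fit with a block called 59.7%, 98.5% and 98.5%. With independent libraries, the fit without a block called 1.5%, 44.8% and 93.9%. Each simulated change was equally large in every replicate, whereas that of Cd34 here was 0.68, 3.66 and 4.93 in replicates 1, 2 and 3. The simulated shares therefore do not apply to genes whose change varies between replicates. A lack of called genes here does not show that few genes changed.

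The alternative fits set beforehand were a block by title or description number, the mean of CD34-negative replicates 3 and 4 as 1 sample, quantile normalization, median-ratio scaling, 2 other filters, 2 other pseudocounts, limma without trend or with robust estimation, and leaving out each library. A further 19 fits were chosen after seeing that these called almost no gene. These left out both replicate 1 libraries with or without the block, or used a correlation within description numbers. Others used library weights with or without the block, or the kind of library as a covariate. The rest changed 1 other choice in the fit with the block. The library weights without the block were 6.95 for CD34-positive replicate 1 and 0.25 to 1.68 for the other libraries. With the block they were 4.59 for CD34-positive replicate 3 and 0.41 to 1.15 for the others. Each weighted fit therefore leaned on 1 CD34-positive library.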

Results

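Gene expression was measured in EML cells sorted by the surface marker CD34, with 4 CD34-negative and 3 CD34-positive libraries. The series title concerns lineage selection and self-renewal in a multipotent precursor, and the comparison asks how cells with and without CD34 differ. Values are FPKM, and the depth of the libraries is unknown. Between 8606 and 9117 genes reached 1 FPKM in each library. The libraries fell into 2 kinds that crossed the groups. Ribosomal protein genes held 27.5% to 36.9% of the summed FPKM in replicates 1 and 2 of both groups, but 2.3% and 4.2% in CD34-negative replicates 3 and 4 and 3.8% in CD34-positive replicate 3. The first principal component, with 67.1% of the variance, separated these 3 libraries from the other 4.

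Cd34, which encodes the sorted marker, was higher in every CD34-positive library than in every CD34-negative one. It averaged 186 ± 61.1 FPKM (SD, n = 3) in CD34-positive and 30 ± 41.9 FPKM (SD, n = 4) in CD34-negative cells. The CD34-negative libraries ranged widely. Cd34 stood at 91.8 FPKM in CD34-negative replicate 1, against 147 FPKM in CD34-positive replicate 1, and at 19.3, 2.67 and 6.02 FPKM in CD34-negative replicates 2, 3 and 4. The difference was 3.60 on the log2 scale (SE 0.98) and did not pass in limma (adjusted p = 0.647, or 0.0931 with the replicate block). It was 0.68 in replicate 1, 3.66 in replicate 2 and 4.93 in replicate 3.

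No gene passed an adjusted p of 0.05 in limma in either direction, and the smallest adjusted p was 0.256. With the replicate block none passed in limma either (smallest adjusted p = 0.0767; 1188 higher and 846 lower at an unadjusted p under 0.05). Without CD34-negative replicate 1, 7 genes passed as higher and 3 as lower. At an unadjusted p under 0.05, 313 genes were higher and 210 lower in CD34-positive cells, where chance alone would give 463 of 9259. In 526 genes the 2 groups did not overlap, 247 higher and 279 lower, which is 5.7% of genes, the share that chance gives (5.7%) if the 7 libraries are taken as exchangeable. That share takes no account of the pairs, and neither does the fit behind the 313 and 210. The 463 is the chance count for any fit over these genes whose assumptions hold. With the replicate block, the 1188 higher and 846 lower genes stand well above it. Genes are not independent of each other, so no p-value is given for that excess. Within replicates, 54% of genes had the same sign in all 3, against 25% for independent signs. The counts without the replicate 1 libraries, a choice made after seeing the data, were 233 higher and 81 lower with the block and 0 in each direction without it.

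Of 18 tested erythroid regulators and membrane genes, 15 had lower values in CD34-positive cells in all 3 replicates and 12 passed as lower in limma adjusted over the list alone (0 over all genes; 13 over the list alone with the block). Gata1, a transcription factor required for erythroid maturation, averaged 14.9 ± 9.74 FPKM (SD, n = 3) in CD34-positive and 90.3 ± 51.7 FPKM (SD, n = 4) in CD34-negative cells, a log2 difference of -2.62 (SE 0.59). Klf1, which activates globin genes, averaged 2.97 against 67.5 FPKM, and the carbonic anhydrase Car1 6.23 against 161 FPKM. Epor, the erythropoietin receptor, averaged 4.10 against 21.3 FPKM. The transferrin receptor Tfrc (72.3 and 83.9 FPKM) and Tal1 (132 and 139 FPKM) differed by less than their spread. The list passed with camera (adjusted p = 4.95e-21, median log2 difference -2.30), and did not with an estimated correlation (adjusted p = 0.295). Between 10 and 13 members passed over the list alone when any 1 library was left out, and between 9 and 14 with the block.

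Among 15 tested genes of globins and heme synthesis, 13 were lower in all 3 replicates and 2 passed in limma adjusted over the list alone, Alad and Cpox (0 over all genes; 11 over the list alone with the block). Alad, an early enzyme of heme synthesis, averaged 4.0 ± 0.81 FPKM (SD, n = 3) against 33.7 ± 22.9 FPKM (SD, n = 4), and Cpox, a later one, averaged 5.80 against 24.3 FPKM. The adult globin Hbb-b1 varied widely, at 254 ± 327 FPKM in CD34-positive and 406 ± 668 FPKM in CD34-negative cells, with log2 differences of -3.71, -1.17 and 0.83 in replicates 1, 2 and 3, and did not pass. The list passed with camera (adjusted p = 1.96e-13), and did not with an estimated correlation (adjusted p = 0.295). Over the list alone, 0 members passed without CD34-positive replicate 2 or 3, 3 without CD34-negative replicate 1 and 6 without CD34-negative replicate 3. With the block, 0 passed without either replicate 2 library. Without a block, 5 passed with the mean of CD34-negative replicates 3 and 4 as 1 sample, 6 with quantile normalization, 7 with pseudocount 0.1 and 0 without both replicate 1 libraries, the last a choice made after seeing the data.

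Part of the mast cell programme was also lower in CD34-positive cells. Of 15 tested mast cell, basophil and eosinophil genes, 4 passed in limma adjusted over the list alone, all lower (0 over all genes; 4 lower and 1 higher with the block). They were Ms4a2, a chain of the IgE receptor, at 2.12 ± 1.63 FPKM (SD, n = 3) against 27.3 ± 20.9 FPKM (SD, n = 4), Hdc, which makes histamine, at 7.52 against 224 FPKM, and the proteases Cma1 at 173 against 2000 FPKM and Mcpt4 at 16.0 against 559 FPKM. Other members had higher values and did not pass in the fit without a block. Cpa3, a mast cell carboxypeptidase, averaged 2400 FPKM in CD34-positive and 1466 FPKM in CD34-negative cells, and the receptor chain Il5ra, which passed as higher over the list alone with the block, averaged 4.42 against 1.29 FPKM. CD34-negative replicate 3 held the most Mcpt4 (1752 FPKM) and CD34-negative replicate 4 the least of that group (43.5 FPKM). The list passed with camera (adjusted p = 2.53e-08), and did not with an estimated correlation (adjusted p = 0.337). Over the list alone, 2 members were lower without CD34-positive replicate 1, 1 without CD34-positive replicate 3 and 7 without CD34-negative replicate 4. With the block, 0 passed without either replicate 2 library or CD34-positive replicate 3, and 7 and 8 were lower without CD34-negative replicates 3 and 4. Without a block, 2 were lower without a filter on low values, 7 with the mean of CD34-negative replicates 3 and 4 as 1 sample, and 1 without both replicate 1 libraries, a choice made after seeing the data.

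**Figure D1:**
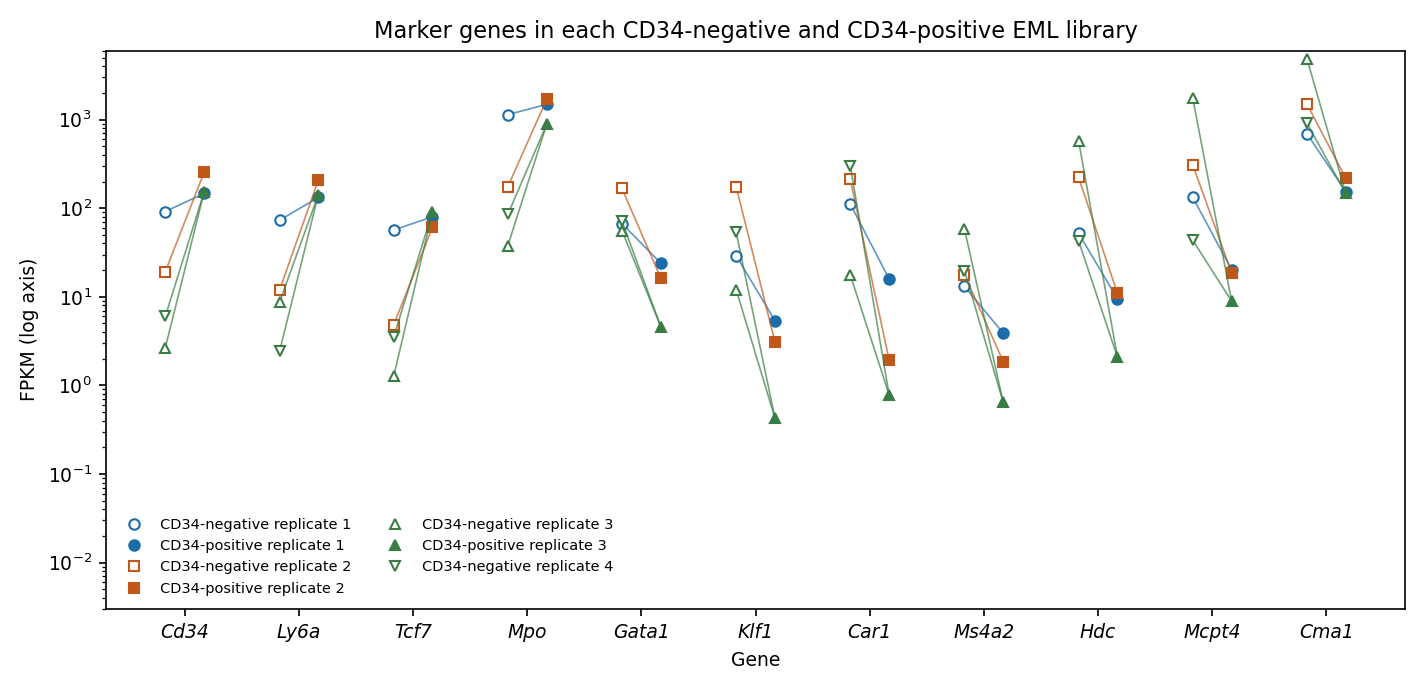
FPKM on a log axis of 11 genes in each library, with open symbols for CD34-negative and filled symbols for CD34-positive libraries and lines joining libraries of the same description number. Cd34 ranges from 2.67 to 91.8 FPKM over the CD34-negative libraries and lies above that in all 3 CD34-positive libraries.

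Of 13 tested neutrophil and monocyte genes, 9 had higher values in CD34-positive cells in all 3 replicates, and 1 passed as higher in limma adjusted over the list alone, the repressor Gfi1 (2.87 against 0.64 FPKM; 0 over all genes, 6 over the list alone with the block). Mpo, the granule enzyme myeloperoxidase, averaged 1355 ± 421 FPKM (SD, n = 3) against 360 ± 524 FPKM (SD, n = 4) and did not pass. Of 23 tested stem and progenitor genes, 5 passed adjusted over the list alone (0 over all genes; 16 with the block). Gfi1, Ly6a, Hlf and Tcf7 were higher and Gata2 was lower. Ly6a, which encodes the stem cell antigen Sca-1, averaged 161 ± 40.9 FPKM against 24.0 ± 33.0 FPKM, and the Wnt pathway transcription factor Tcf7 averaged 77.1 ± 15.1 FPKM against 16.6 ± 26.9 FPKM. Gata2 averaged 85.6 FPKM in CD34-positive and 295 FPKM in CD34-negative cells. Kit (222 and 266 FPKM) and Runx1 (37.2 and 36.0 FPKM) differed by less than their spread. Of 9 tested B and T lymphoid genes none passed adjusted over the list alone (5 with the block, 4 without CD34-negative replicate 1). Tcf7 and Cd7 (25.9 against 7.54 FPKM) had the smallest adjusted p. Gfi1 and Tcf7 are each members of more than 1 list. In the fit of the 2 groups alone, leaving out any 1 library but CD34-negative replicate 1 left 0 neutrophil and monocyte and 0 stem and progenitor genes over the list alone, and leaving out that one gave 4 and 10. With the mean of CD34-negative replicates 3 and 4 as 1 sample 0 of either passed, and with pseudocount 0.1 or a filter of 5 FPKM, which removes Gfi1, 0 neutrophil and monocyte genes and 2 and 3 stem and progenitor genes did. Without a filter 2 stem and progenitor genes and 2 neutrophil and monocyte genes passed, and 1 lymphoid gene passed as lower. Other settings raised the counts. Quantile normalization gave 3 neutrophil and monocyte genes, 2 lymphoid genes, and 6 higher and 1 lower stem and progenitor genes. Median-ratio scaling gave 7 higher and 1 lower stem and progenitor genes, and a filter of 5 FPKM gave 2 lymphoid genes. With the block, 0 genes of these 3 lists passed without either replicate 2 library or CD34-positive replicate 3, and 11 neutrophil and monocyte genes passed without CD34-negative replicate 3.

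These 3 lists passed with camera, the neutrophil and monocyte list at an adjusted p of 2.84e-06, the stem and progenitor list at 0.000603 and the lymphoid list at 0.00785. With an estimated correlation none did (adjusted p = 0.295, 0.488 and 0.473). Without CD34-negative replicate 2 the stem and progenitor list had an adjusted p of 0.102 and the lymphoid list of 0.165, and without CD34-positive replicate 3 they had 0.0685 and 0.181. The lymphoid list also had 0.302 without a filter on low values and 0.101 with library weights, a choice made after seeing the data.

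The interferon response list (10 tested, median log2 difference 0.65) and the MHC class II and antigen presentation list (9 tested, 0.46) also passed with camera as higher in CD34-positive cells, at adjusted p of 0.000379 and 0.0382, and neither did with an estimated correlation (adjusted p = 0.424 and 0.473). No member of either passed in limma adjusted over the list alone (3 and 1 with the block, and 0 of either with the block without either replicate 2 library or CD34-positive replicate 3; with the block they were 7 and 3 without either replicate 1 library). The interferon members with the smallest p lay near the minimum of 1 FPKM. They were Igtp (3.33 against 1.46 FPKM), Ddx58 (2.49 against 0.89 FPKM), Usp18 (1.95 against 1.05 FPKM) and Xaf1 (1.83 against 0.76 FPKM). The antigen-presentation members with the smallest p were Cd74 (6.54 against 2.61 FPKM) and the light chain B2m (618 against 283 FPKM). Without CD34-positive replicate 3 the adjusted p of the lists were 0.0685 and 0.0832, and the second list also had 0.0627, 0.0646 and 0.130 without CD34-negative replicates 2, 3 and 4 and 0.0520 without CD34-positive replicate 1. The interferon list had 0.0596 with a filter of 5 FPKM. The antigen presentation list passed in 15 of 32 other settings, some of which are nearly the same fit. It had 0.0774 with quantile normalization, 0.0579 without a filter and 0.0543 with a filter of 5 FPKM. It had 0.0853 with the mean of CD34-negative replicates 3 and 4 as 1 sample and 0.0839 with the block by title number.

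**Figure D2:**
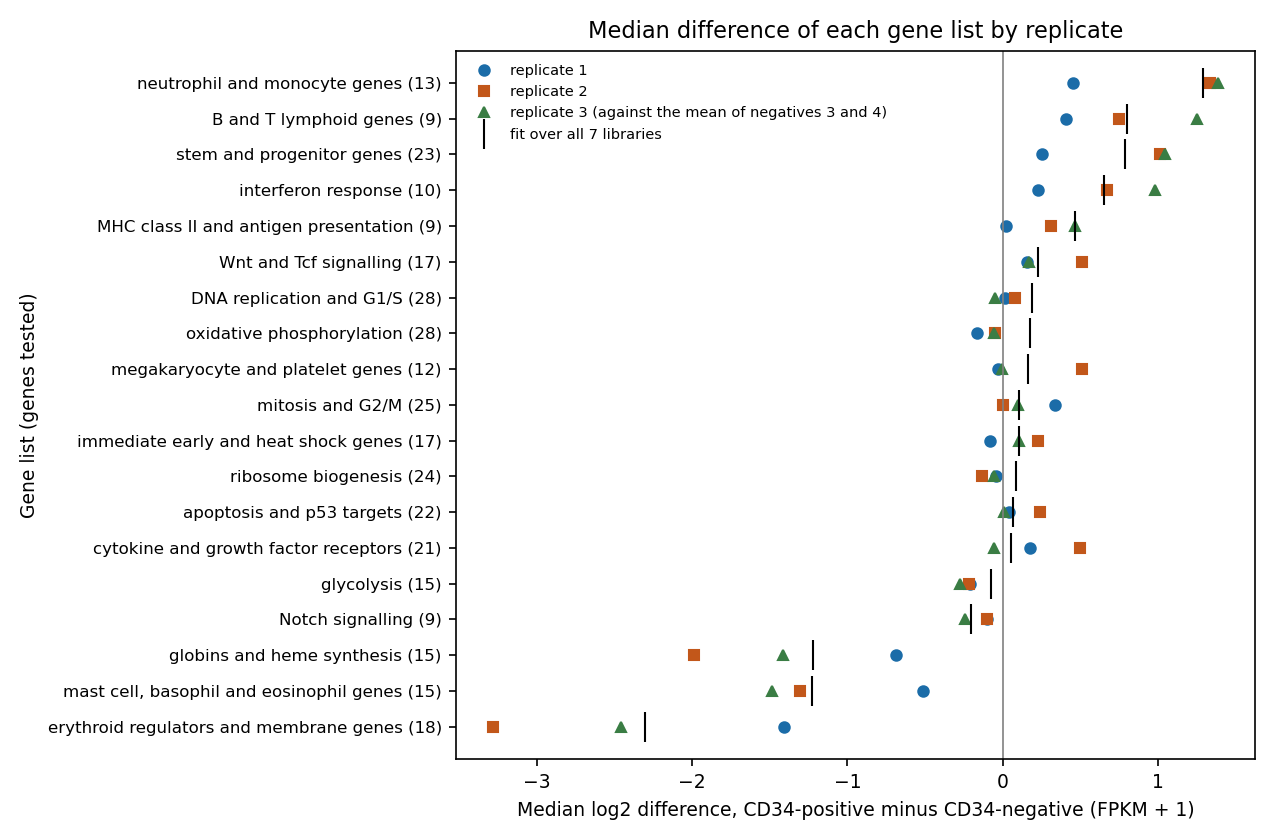
Median log2 difference, CD34-positive minus CD34-negative, of each gene list with at least 9 tested genes, by replicate (symbols) and over all 7 libraries (vertical marks). The erythroid list has medians of -1.41, -3.28 and -2.46 in replicates 1, 2 and 3.

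The other 13 lists did not pass in the fit of the 2 groups alone. Wnt and Tcf signalling had an adjusted p of 0.125 (0.0403 with the replicate block, but adjusted p = 0.551 with the block and an estimated correlation), with no member but Tcf7 and Lrp5 passing over the list alone with the block. Notch signalling had 0.0937, and its target Hes1 passed adjusted over the list alone at 1.02 against 20.4 FPKM (2 higher and 3 lower with the block; 0 without a filter on low values, with 21 tested). Cytokine and growth factor receptors had 0.505, with 4 members lower (Epor, Ifngr1, Csf2rb and Csf2rb2) and 5 higher (among them Il6st, Il2rg, Acvr1b and Tgfbr1) over the list alone with the block and 0 in the fit of the 2 groups alone. DNA replication and G1/S (0.505), mitosis and G2/M (0.799), ribosome biogenesis (0.799) and immediate early and heat shock genes (0.764) held no member past the threshold over the list alone in the fit of the 2 groups alone or with the block. Apoptosis and p53 targets (0.505), glycolysis (0.764) and megakaryocyte and platelet genes (0.862) held none in the fit of the 2 groups alone. With the block, 4 apoptosis genes were lower, among them Gadd45a, Bid and Bax, and Bcl2l1 and Pmaip1 were higher, Slc2a3 and Hk1 were lower and Pdk1 higher among glycolysis genes, and the platelet glycoprotein Gp5 was lower. With the block, 0 members of the 13 lists passed over the list alone without either replicate 2 library, and without CD34-positive replicate 3 only 1 apoptosis gene did. Oxidative phosphorylation had 0.848, and 0.0490 in the lower direction with the block, but adjusted p = 0.551 with the block and an estimated correlation. Of the lists for other cell types, the stromal and endothelial list had 2 tested genes, Pdgfrb and Pecam1 (adjusted p = 0.0927; both higher over the list alone with the block), and the hepatocyte list 1, Trf (0.0642), which passed over the list alone but not without CD34-negative replicate 2 or 4 or any 1 of the CD34-positive replicates, nor with quantile normalization, without a filter or with the mean of CD34-negative replicates 3 and 4 as 1 sample. Several of these lists passed when 1 library was left out. Without CD34-negative replicate 1, Wnt signalling had 0.0409, the stromal list 0.0411 and the hepatocyte list 0.0256. Without CD34-negative replicate 2, DNA replication had 0.0160, receptors 0.0438 and oxidative phosphorylation 0.0160. Without CD34-negative replicate 3, ribosome biogenesis had 0.0448. Without CD34-positive replicate 2, glycolysis had 0.0157, oxidative phosphorylation 0.0332, and Wnt signalling and the stromal list 0.0409. Without CD34-positive replicate 3, DNA replication had 0.0308 and oxidative phosphorylation 0.00880. The camera direction was down while the median difference was above 0 for the megakaryocyte, receptor, ribosome biogenesis, apoptosis and immediate early lists.

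Ranked by size among genes whose groups do not overlap, the 10 highest in CD34-positive cells were Cd34, Ly6a, Tcf7, S100a4, Ugt1a7c, P2rx3, Nrgn, Gem, Prss16 and Cdh17. Among the 10 lowest were Car1, Hdc, Atp1b2, Mcpt4, Acp5, Klf1, Ermap, Mcpt2 and Csrp3. None passed over all genes. Atp1b2, a sodium pump subunit, averaged 12.5 ± 10.4 FPKM (SD, n = 3) against 189 ± 74.1 FPKM (SD, n = 4), and S100a4, a calcium-binding protein, averaged 268 ± 180 FPKM against 37.5 ± 33.4 FPKM.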

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

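The tests of replicate 1, of a scaling factor per library and of the 2 CD34-negative replicates below were chosen after the results were seen. In the CD34-negative group, 11 of 93 named genes had 1 library far from the other 3 on the log2 scale, where chance flags about 1 in 20 of independent normal values. The libraries fall into 2 kinds and many named genes share a list, so these values are not independent. The share over all tested genes is not given here, so 11 of 93 cannot be read as an excess. The values are the gap to the nearest library over the group's range. CD34-negative replicate 1 stood apart for Hlf (0.849), Cebpe (0.937), Dntt (0.84), Ugt1a7c (0.874) and P2rx3 (0.959), each time on the high side. CD34-negative replicate 3 stood apart for Gata2 (0.837), Gp1ba (0.839) and Fosb (0.925). CD34-negative replicate 2 stood apart for Runx1 (0.832) and E2f2 (0.857), and CD34-negative replicate 4 for Hk2 (0.877).

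The pair of replicate 1 differed least, with an SD over genes of its log2 differences of 0.35, against 0.72 in replicate 2 and 0.64 in replicate 3. A swap of the 2 labels is argued against, since 5.56% of the erythroid members had the other sign in replicate 1 and Cd34 was higher in the CD34-positive library. CD34-positive cells in the CD34-negative replicate 1 library could give the pattern, and 52 genes at least 8-fold higher in replicates 2 and 3 had a median ratio of negative to positive of 0.627 in replicate 1 with a quartile ratio of 1.34. That test cannot decide, because all tested genes give a quartile ratio of 1.31 (4 ways of choosing the genes were tried and gave 1.16 to 1.34). The 53 genes at least 8-fold lower in replicates 2 and 3 had a median ratio of 5.68 and a quartile ratio of 2.56, so they kept more of their difference than the higher genes, but this asymmetry was not tested, and such cells and a smaller difference between the sorted cells of that replicate both stay open.

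Ribosomal protein genes were far lower in CD34-negative replicates 3 and 4 and CD34-positive replicate 3 than in the other 4 libraries, and microRNA and small nucleolar RNA symbols held 39.3%, 15.7% and 7.9% of their summed FPKM against at most 0.3%. Most of this in the first 2 is 1 symbol, Mir703, at 149618 and 35989 FPKM, which is listed at 0 in CD34-positive replicate 3. One scaling factor per library is argued against, since the ribosomal protein genes lay at -5.16 relative to all tested genes on the log2 scale. The ribosomal protein genes lay at -4.08 relative to genes of matched length, which had a median of -1.38, while genes over 3 kb had 0.13. Those genes were matched on length only, not on expression. Genes with lower values cannot fall as far on the log2(FPKM + 1) scale, so this comparison cannot decide on loss of short transcripts. A different library preparation or annotation could also give the pattern and was not tested, and no biological explanation was tested. The kind of library crosses the groups.

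CD34-negative replicates 3 and 4 share a description number but differed in lineage genes. The mast cell list was higher in replicate 3 by a median of 2.33 (15 of 15 members) and the erythroid list stood at -1.72 (0 of 18 members higher). A general difference of genes at that expression level is argued against, since the medians lay at percentiles 100 and 0 of 10000 random lists matched on mean expression. Different shares of mast and erythroid cells in the 2 sorted samples may account for it and were not tested.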

How the results depend on the processing

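The 19 fits chosen after seeing that planned fits called almost no gene are called added. Of 18 planned refits over all genes, 17 called no gene. Of the 19 added, 10 called none, 9 at least 1 and 7 over 100, so the zero counts depend on how the libraries are weighted, paired or left out. Each weighted fit leaned on 1 CD34-positive library. Genes higher, lower and changed at least 2-fold in added fits were 233, 81 and 311 without both replicate 1 libraries with the replicate block, 345, 249 and 358 with a correlation within description numbers, 304, 83 and 361 with library weights, and 353, 310 and 334 with library weights and the replicate block. The added replicate block with pseudocount 0.1 gave 0, 4 and 4. The added fits that called no gene were the kind of library as a covariate (smallest adjusted p = 0.185), both replicate 1 libraries left out without a block, the block with pseudocount 5, a filter of 5 FPKM, robust estimation, no trend or quantile normalization, and the block without CD34-negative replicate 2 or 4 or CD34-positive replicate 2. Leaving out 1 library gave 0 to 231 higher, 0 to 125 lower and 0 to 310 changed at least 2-fold over the planned and added blocked fits. Of the planned ones only that without CD34-negative replicate 1 called any (7, 3 and 10). With the added block these were 231, 81 and 310 without CD34-negative replicate 1, 230, 81 and 309 without CD34-positive replicate 1, 32, 125 and 141 without CD34-negative replicate 3, and 1, 0 and 1 without CD34-positive replicate 3. The cause was not tested.

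The Cd34 difference kept its direction in every fit (2.17 to 4.63, adjusted p from 0.0123 to 0.999969). It passed only in added fits. It was 4.39 with the block without either or both replicate 1 libraries, which are nearly the same fit. It was 3.30 with the correlation within numbers, 4.23 with library weights and 3.27 with weights and block.

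The number of lists past the threshold was 8, 7 and 10 with the replicate block by title or description number, and 6 to 12 when 1 library was left out. It was 0 with an estimated correlation and 0 with fry, whose lowest adjusted p was 0.347. The erythroid, globin, neutrophil and mast cell lists passed with camera in all 32 other settings, some of which are nearly the same fit. Oxidative phosphorylation changed direction and passed at medians of -0.0817 with the replicate block, -0.0758 with the block and pseudocount 5, -0.107 with weights and block, -0.260 without CD34-positive replicate 2, and in added blocked fits -0.134 without either replicate 2 library, -0.112 without CD34-negative replicate 3 and -0.0920 without CD34-positive replicate 3. It passed as higher at 0.583 without CD34-negative replicate 2, 0.683 without CD34-positive replicate 3 and 0.788 with library weights. The block by description number also moved Wnt signalling past the threshold (0.0403), the block by title left out the MHC class II list, and the block changed no other call over all genes. Other lists past the threshold were mitosis with the added block without either replicate 2 library (0.00544), ribosome biogenesis with the added block without CD34-negative replicate 3 (0.00413), the hepatocyte list with median-ratio scaling (0.0432) or without both replicate 1 libraries (0.0205, added), the stromal list with the added block and pseudocount 5 (0.0497), and Wnt signalling in 4 added fits with the block (0.0270 to 0.0373). Settings that alter only the gene-wise variance were not run for lists. The median log2 difference of all genes was 0.09, and -0.01 with quantile normalization or median-ratio scaling. It was 0.28 with library weights, the fit with 304 higher and 83 lower genes, 0.16 without CD34-negative replicate 1, 0.19 without CD34-positive replicate 3 and 0.00 without CD34-positive replicate 1. Unknown depth limits what low genes can show.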

Other observations

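The tests of single lists against other splits and the count among the splits that follow the description numbers below were chosen after the results were seen. Among growth factor receptors, 5 members were higher and 4 lower over the list alone with the replicate block, and 0 in the fit of the 2 groups alone or with the block without either replicate 2 library or CD34-positive replicate 3. The receptor chains Csf2rb (95.0 against 233 FPKM) and Csf2rb2 (84.1 against 279 FPKM) had lower values in CD34-positive cells in all 3 replicates, and the shared chain Il2rg (96.7 against 48.7 FPKM) had higher values. The embryonic globins Hbb-bh1 (0.89 against 88.0 FPKM) and Hbb-y (7.37 against 64.8 FPKM) had lower values in CD34-positive cells in all 3 replicates. Neither passed over the list alone in the fit of the 2 groups alone. Hba-x was listed at 0 in the 3 CD34-positive libraries, and its CD34-negative values are not reported here, so no difference is drawn from it.

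Differences within replicates went together across genes, which are not independent replicates. Of 9259 genes, 54% had the same sign in all 3 replicates, where independent signs would give 25%. The correlation across genes was 0.63 between replicates 1 and 2, 0.56 between 1 and 3 and 0.74 between 2 and 3. Of the 314 genes called without replicate 1 with the block, 303 had the same sign in replicate 1. The share among genes not called is not given here, so this number has no baseline beside it.

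All 35 splits of the 7 libraries into 3 and 4 were refitted. Since the real split called 0 genes, 35 of 35 splits gave as many higher genes, 35 as many lower genes and 35 as many changed at least 2-fold. A count of 0 fixes that outcome, so it decides nothing about chance. The highest other split, which parts the 3 libraries with low ribosomal protein values from the other 4, called 554 higher, 2730 lower and 2152 changed at least 2-fold, which points to that structure of the libraries. For lists, 15 of 35 splits gave at least 8, and the highest other gave 15, so chance cannot be excluded for the number of lists. Among the 12 splits that set 1 library of each description number against the rest, as the real one does, 6 gave at least 8 lists with the real one included, and the highest other gave 15. By single list, the splits of 35 with a camera p as small as the real one, and those with a median as large, numbered 1 and 2 for the neutrophil and monocyte list, 2 and 2 for the erythroid, 3 and 6 for the globin, 3 and 3 for the interferon, 4 and 7 for the MHC class II, 5 and 7 for the mast cell, 8 and 5 for the stem and progenitor and 8 and 8 for the lymphoid list. A share of 1 in 35 is the smallest that these splits can give, and they include splits that do not part the pairs, so they settle nothing for 21 lists.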
